A study of Rattus norvegicus with 25 samples.

How the data were processed

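Clariom S Rat arrays were run on RNA from the spinal cord of 25 rats, 5 in each of 5 groups, as the labels give them: uninjured, injury alone at 7 d and 28 d, and injury with AAV5-GfaABC1D-dYFP at 7 d and 28 d. Per the labels' protocols, animals weighed 220 to 250 g, RNA had an integrity number above 8.8, and 200 ng was labelled. The label of the uninjured animals does not say whether they had surgery without contusion. The labels call the arrays of a group biological replicates.

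The deposited values are on a log2 scale, and per the submitters' processing notes the authors used Transcriptome Analysis Console, whose version is not given in the sources used here. The summarisation method, the annotation version and detection calls are also not given in the sources used here. That the base is 2 was inferred from the range of the values, 2.44 to 19.7. With that base some values lie above 16, the log2 limit of a 16-bit scanner. How they arose is not given in the sources used here, so a fold is a fold on the deposited scale. Array medians lay between 7.27 and 7.47 and upper quartiles between 10.0 and 10.3, so the values were used as deposited, without another normalization. There were no missing values, no control probes and no duplicate columns. No background level is at hand, so signals near the floor carry no statement on presence.

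Of 23188 transcript clusters, 15049 carry 1 gene symbol in the platform annotation, 0 carry several and 8139 carry none. They name 15037 genes. For the 10 genes with more than 1 cluster, the cluster with the highest mean over all arrays stands for the gene, and in 2 of them the clusters differed in an injury call. Without a genome of the array's build, no coordinates are given.

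The tests were fixed before the data were examined. A linear model with 1 mean per group was fitted to all 25 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation without trend, and each contrast was tested two-sided. The residual degrees of freedom were 20 and the prior added 6.90. All p-values called adjusted are Benjamini-Hochberg values, from limma over 23188 clusters for genes and from limma's camera over 27 lists for lists. Adjusted p under 0.05 was called. The median standard error of a difference between groups was 0.169 log2 units, and the median 95% confidence interval reached 0.347 to either side.

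The 27 gene lists hold 435 genes, of which 374 were measured, and were written from general knowledge of cord tissue. Camera was run with a preset correlation of 0.01, and again with the correlation estimated from the data. Fry, a rotation test of whether the genes of a list move one way on balance, and an exact permutation of list means between arrays were run beside it. Lists named for a cell type describe transcripts of the tissue and not cell numbers.

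Genes were named by a rule fixed beforehand. It takes the 8 highest and 6 lowest changes past the test for the 3 comparisons of injury alone, among genes whose groups do not overlap. For vector comparisons it takes the 4 genes with the smallest unadjusted p where none passed. To these come up to 4 genes per list with the smallest p, and 20 genes reported for every comparison.

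The gene and list tests were tested on simulated data built from these arrays, with known fold changes. The simulated noise was drawn independently for each gene, so these data cannot show how genes that vary together affect the list test. Alternatives were other normalizations (quantile and cyclic loess), dim clusters left out (those under the 30th percentile), array weights, a trended robust prior, only the groups compared, a replicate block, named clusters only, other thresholds, the mean over all clusters of a gene, and each array left out in turn. The runs without 2 arrays that carry muscle transcripts (vector replicates 1 and 3 at 7 d) or without 3 (also replicate 2 at 28 d), the permutation of list means and the gene families were added after seeing the data. A result was called reversed under an alternative only where a value past the test in either run changed sign, and a count was called moved where it changed by more than 1.5 times.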

Results

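Gene expression was measured in thoracic spinal cord of adult female Sprague-Dawley rats with Clariom S Rat arrays, which report the signal of 23188 transcript clusters. There were 25 arrays in 5 groups of 5 animals: uninjured cord, contused cord at 7 d and at 28 d, and contused cord at 7 d and at 28 d from animals that had also received AAV5-GfaABC1D-dYFP at surgery. This reporter vector is an adeno-associated virus of serotype 5 that places a yellow fluorescent protein under a short GFAP promoter, and it was microinjected into the cord at 4e+09 vector genomes in 4 uL. Injury-alone animals are labelled as having no treatment, so the vector groups differ from them by both the injection and the vector. An Infinite Horizons impactor delivered 175 kDyn at T10, per the labels' protocols, and 5 mm of cord centred on the lesion was taken. The labels call the arrays biological replicates, and the number of arrays limits the precision. Array medians lay between 7.27 and 7.47 on the log2 scale. Arrays of one group correlated with each other at a mean Pearson r across clusters of 0.992 in uninjured cord, 0.991 and 0.993 in injury alone at 7 d and 28 d, and 0.988 and 0.991 in the vector groups at 7 d and 28 d.

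Values below are log2 differences between group means ± SE with 5 animals per group, unless a median over a gene list is named. The SE, interval and p-value of a gene come from the moderated fit to all arrays. They rest on a spread pooled over all groups and not on that of the groups compared. Where groups differ in spread, they can be too small or too large for a single comparison. A gene is said to have risen or fallen only at an adjusted p under 0.05 in limma, and where one direction is given for a list, 0 of its genes passed in the other. Beside each count stands the count adjusted over the list alone. The adjusted p of a list is that of camera, which sets the genes of the list against all other genes with a preset correlation between them.

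The first comparison set injury alone at 7 d against uninjured cord. Of the 27 lists phagocytes and lysosome had the highest median (3.57) and cholesterol synthesis the lowest (-2.28). Gpnmb, a membrane glycoprotein of lipid-laden phagocytes, rose by 8.45 ± 0.30 (adjusted p = 1.9e-17), from 8.90 ± 0.66 to 17.4 ± 0.64 (SD). Cd68, a lysosomal protein of macrophages, rose by 8.14 ± 0.33, and Mmp12, the macrophage elastase, by 7.87 ± 0.58. Ifitm1, an interferon-induced membrane protein, rose by 7.55 ± 0.44, and the beta-glucan receptor gene Clec7a by 7.22 ± 0.30. Rises were also large for the inhibitory receptor gene Lilrb4 (6.93 ± 0.49), the Fc receptor-like gene Fcrl2 (6.87 ± 0.77) and the macrophage lectin gene Siglec1 (6.87 ± 0.45). At the other end, Scd, the stearoyl-CoA desaturase, fell by 3.42 ± 0.17 (adjusted p = 8.3e-15). Fdft1, the squalene synthase, fell by 2.91 ± 0.21, the sterol-sensing regulator Insig1 by 2.78 ± 0.16, the lanosterol demethylase Cyp51 by 2.65 ± 0.19, the sterol reductase Tm7sf2 by 2.65 ± 0.20 and the acetyl-CoA synthetase Acss2 by 2.58 ± 0.17.

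Among myeloid lists, 21 of 22 measured genes of phagocytes and lysosome rose (21 adjusted over the list alone), with a median of 3.57 (adjusted p = 2.8e-32). Lgals3, a galectin of activated phagocytes, rose by 5.50 ± 0.26 and Ctsd, a lysosomal protease, by 3.09 ± 0.15. All 10 genes of homeostatic microglia rose (10 adjusted over the list alone), with a median of 1.87 (adjusted p = 2.8e-13). They included Csf1r, the receptor that sustains microglia, at 3.34 ± 0.15, Gpr34 at 3.01 ± 0.14 and the fractalkine receptor gene Cx3cr1 at 2.44 ± 0.15. All 13 complement genes rose (13 adjusted over the list alone, median 2.69, adjusted p = 7.3e-17), among them C1qb at 4.82 ± 0.26, C1qa at 3.67 ± 0.20 and the integrin subunits of complement receptor 3, Itgb2 at 4.85 ± 0.24 and Itgam at 3.36 ± 0.19. The pan-leukocyte gene Ptprc rose by 4.18 ± 0.22 and the microglial gene Aif1 by 3.41 ± 0.24.

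Of 16 reactive astrocyte genes, 12 rose (13 adjusted over the list alone), with a median of 1.76 (adjusted p = 3.1e-12). Gfap, the astrocyte intermediate filament, rose by 0.45 ± 0.11 (adjusted p = 0.0013), Vim by 1.99 ± 0.13 and Nes by 1.06 ± 0.22. The protease inhibitor gene Timp1 rose by 4.80 ± 0.31, the iron-binding acute-phase gene Lcn2 by 4.22 ± 0.54, Lgals3bp by 4.18 ± 0.26 and the hyaluronan receptor gene Cd44 by 2.37 ± 0.18. In the list of genes described as A1-type, 5 of 9 rose and 1 fell (5 and 1 adjusted over the list alone, median 1.73, adjusted p = 2.2e-04, adjusted p = 0.0828 with an estimated correlation), with Gbp2 at 2.99 ± 0.37, C3 at 2.69 ± 0.28 and Ggta1 at 2.12 ± 0.17. In the A2-type list 6 of 10 rose (6 adjusted over the list alone, median 0.90, adjusted p = 0.0012, adjusted p = 0.139 with an estimated correlation), with the endotoxin co-receptor gene Cd14 at 3.97 ± 0.40. Of 15 homeostatic astrocyte genes 2 rose and 8 fell (3 and 9 adjusted over the list alone), and the list did not pass (median -0.43, adjusted p = 0.0504). The amino acid transporter gene Slc7a10 fell by 2.16 ± 0.28, the gap junction gene Gjb6 by 1.75 ± 0.21 and the potassium channel gene Kcnj10 by 1.61 ± 0.19, whereas Mlc1 rose by 0.87 ± 0.12. The water channel gene Aqp4 differed by -0.18 ± 0.12 (adjusted p = 0.293).

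Interferon response genes rose in 23 of 25 cases (24 adjusted over the list alone, median 2.48, adjusted p = 3.3e-16). The antiviral GTPase gene Mx1 rose by 6.18 ± 0.50, Rsad2 by 4.81 ± 0.41, Oasl2 by 3.98 ± 0.36 and Ifi47 by 3.68 ± 0.34, and smaller rises were seen in Isg15 (2.63 ± 0.46) and Cxcl10 (2.37 ± 0.41). The list of viral nucleic acid sensing had 11 of 14 genes higher (12 adjusted over the list alone, median 1.89, adjusted p = 6.1e-12), with the endosomal RNA receptors Tlr8 at 4.06 ± 0.36 and Tlr7 at 3.61 ± 0.23, the DNA receptor gene Tlr9 at 1.57 ± 0.20 and the adaptor gene Myd88 at 2.49 ± 0.20. Antigen presentation rose in 8 of 15 genes (10 adjusted over the list alone, median 1.20, adjusted p = 8.1e-07, adjusted p = 0.0663 with an estimated correlation). The costimulatory ligand gene Cd86 rose by 4.06 ± 0.21 and B2m, the light chain of class I molecules, by 1.57 ± 0.13. Cytokine and chemokine genes rose in 14 of 24 cases and fell in 1 (15 and 1 adjusted over the list alone, median 0.67, adjusted p = 1.7e-06). Tgfb1 rose by 3.57 ± 0.23, Ccl3 by 3.54 ± 0.35 and the monocyte chemoattractant gene Ccl2 by 3.10 ± 0.38. Tnf differed by 0.28 ± 0.20 (adjusted p = 0.327) and Il1b by 0.42 ± 0.18 (adjusted p = 0.0847). Il1b passed without injured replicate 4 (adjusted p = 0.0335) and with array weights (adjusted p = 0.0467).

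For lymphocytes and granulocytes, few list genes passed. Of 20 T and NK cell genes 3 rose and 1 fell (3 and 0 adjusted over the list alone, median 0.06, adjusted p = 0.145). Genes of both CD8 chains rose, Cd8b by 5.19 ± 0.40 and Cd8a by 4.39 ± 0.57, and the costimulator gene Icos rose by 1.17 ± 0.19. Cd3e, a chain of the T cell receptor complex, differed by -0.01 ± 0.25 (adjusted p = 0.978). Among 7 B and plasma cell genes only Cd22 passed, at 1.38 ± 0.36 (1 adjusted over the list alone, list adjusted p = 0.606, with a median of -0.06 and a mean and test in the upward direction). Of 12 neutrophil genes 2 rose (2 adjusted over the list alone, median 0.37, adjusted p = 0.0147, adjusted p = 0.194 with an estimated correlation), the collagenase gene Mmp8 by 6.34 ± 0.66 and the growth factor receptor gene Csf3r by 2.79 ± 0.22. Without injured replicate 2 the neutrophil list did not pass (median 0.11, adjusted p = 0.0544).

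All 19 neuronal genes fell (19 adjusted over the list alone, median -1.31, adjusted p = 6.1e-12, adjusted p = 0.123 with an estimated correlation). The vesicular glutamate transporter gene Slc17a6 fell by 2.17 ± 0.28, the potassium channel gene Kcnc1 by 1.82 ± 0.21 and the NMDA receptor gene Grin1 by 1.75 ± 0.25. In the motor neuron list 3 of 9 genes fell (4 adjusted over the list alone, median -0.40, adjusted p = 0.0412, adjusted p = 0.195 with an estimated correlation), among them Chat, the acetylcholine-synthesising enzyme, by 1.18 ± 0.18. The motor neuron list did not pass without uninjured replicate 5 (adjusted p = 0.0548), injured replicate 4 (adjusted p = 0.0717) or injured replicate 5 (adjusted p = 0.0593). Myelinating oligodendrocyte genes fell in 10 of 13 cases (11 adjusted over the list alone, median -0.57, adjusted p = 2.0e-05, adjusted p = 0.115 with an estimated correlation), with Fa2h, which hydroxylates myelin lipids, at -1.86 ± 0.19, Mog at -1.34 ± 0.15 and Mbp at -0.57 ± 0.10. All 13 genes of cholesterol synthesis fell (13 adjusted over the list alone, median -2.28, adjusted p = 7.3e-17), with Fdps at -2.39 ± 0.15 and the squalene epoxidase gene Sqle at -2.39 ± 0.17. Oligodendrocyte precursor genes went both ways, 4 of 8 up and 1 down (4 and 1 adjusted over the list alone, median 0.39, adjusted p = 0.0741), with the receptor gene Gpr17 at 1.34 ± 0.18 and the transcription factor gene Olig1 at -1.08 ± 0.20.

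Cell division genes rose in 17 of 17 cases (17 adjusted over the list alone, median 2.18, adjusted p = 2.1e-17), with the proliferation marker Mki67 at 4.08 ± 0.31, the nucleotide reductase gene Rrm2 at 3.01 ± 0.23 and Ccna2 at 2.80 ± 0.22. Fibrotic matrix genes rose in 9 of 14 cases (11 adjusted over the list alone, median 1.31, adjusted p = 2.6e-05, adjusted p = 0.239 with an estimated correlation), among them Postn at 3.43 ± 0.61, Fn1 at 1.88 ± 0.40 and Col1a1 at 1.83 ± 0.38. Chondroitin sulfate proteoglycan and tenascin genes went both ways, 5 of 15 up and 4 down (5 and 5 adjusted over the list alone, median 0.12, adjusted p = 0.604). The secreted proteoglycans Ncan and Vcan rose by 1.85 ± 0.16 and 1.79 ± 0.24, and the link protein genes of perineuronal nets, Hapln1 and Hapln4, were at -2.49 ± 0.29 and -2.05 ± 0.25. The remaining lists did not pass. Endothelium and pericytes had 1 of 15 genes higher and 3 lower (1 and 3 adjusted over the list alone, median -0.28, adjusted p = 0.444). Schwann cells had 3 of 10 higher and 1 lower (3 and 1, median 0.03, adjusted p = 0.244), and ependymal cells 3 of 9 lower (3, median 0.05 with a downward mean and test, adjusted p = 0.604). Skeletal muscle had 2 of 12 lower (2, median -0.25, adjusted p = 0.360) and erythroid cells 1 of 8 lower (0, median -0.44, adjusted p = 0.434). The neurotrophin receptor gene Ngfr, in the Schwann cell list, rose by 2.46 ± 0.29, and Pvalb, in the muscle list and also expressed by cord neurons, fell by 2.27 ± 0.33.

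In total 7590 of 23188 transcript clusters passed at 7 d, 3380 higher and 4210 lower, of which 1415 and 1123 changed at least 2-fold. The share of higher calls, 44.5%, was 51.5% after cyclic loess. Of the 27 lists 17 passed, 13 upward and 4 downward, and 9 of these also passed with an estimated correlation: reactive astrocytes, homeostatic microglia, phagocytes and lysosome, complement, interferon response, viral nucleic acid sensing, cytokines and chemokines, cholesterol synthesis and cell division.

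**Figure D1:**
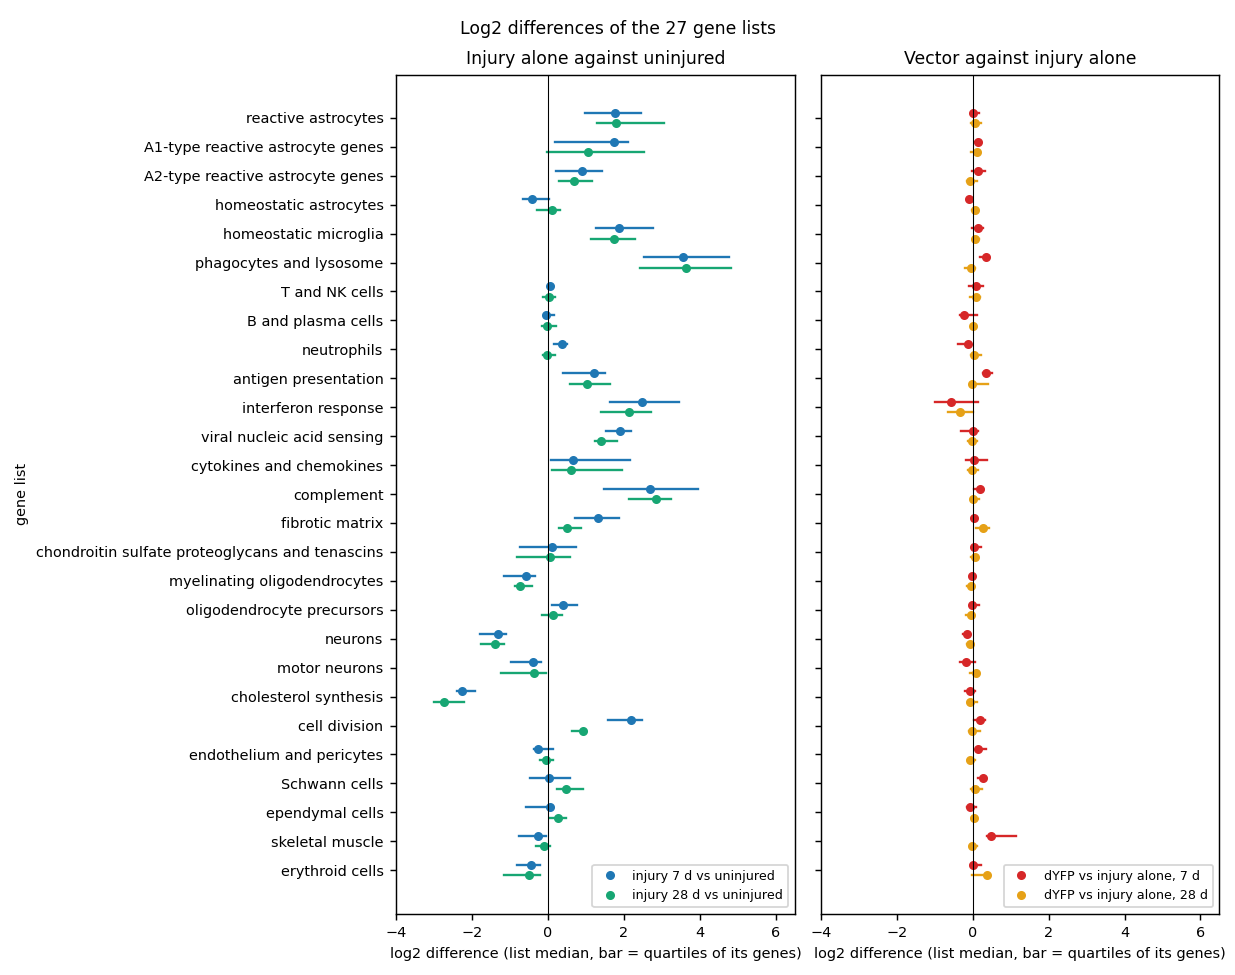
Median log2 difference of each of the 27 gene lists (point) with the quartiles of its measured genes (bar). The left panel shows injury alone against uninjured cord at 7 d (blue) and 28 d (green), where phagocytes and lysosome reach 3.57 and 3.64 and cholesterol synthesis -2.28 and -2.74, and the right panel shows the vector groups against injury alone at 7 d (red) and 28 d (yellow) on the same axis, where skeletal muscle at 7 d has the highest median, 0.49.

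At 28 d the same comparison was made with injury alone at 28 d. Phagocytes and lysosome again had the highest list median (3.64) and cholesterol synthesis the lowest. Gpnmb rose by 8.26 ± 0.30 (adjusted p = 3.6e-17), Cd68 by 7.59 ± 0.33, Clec7a by 7.34 ± 0.30, Ifitm1 by 6.44 ± 0.44, Lgals3 by 6.17 ± 0.26, the cholesterol exporter gene Abca1 by 5.64 ± 0.30, Fcrl2 by 5.64 ± 0.77 and Lilrb4 by 5.59 ± 0.49. Scd fell by 3.90 ± 0.17 (adjusted p = 8.7e-16), Tm7sf2 by 3.54 ± 0.20, the sterol synthesis gene Hsd17b7 by 3.49 ± 0.20, Fdft1 by 3.37 ± 0.21, Cyp51 by 3.18 ± 0.19 and Insig1 by 3.09 ± 0.16. All 13 cholesterol synthesis genes fell (13 adjusted over the list alone, median -2.74, adjusted p = 1.1e-21).

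Phagocyte and lysosome genes rose in 21 of 22 cases at 28 d (22 adjusted over the list alone, median 3.64, adjusted p = 9.5e-34), homeostatic microglia genes in 10 of 10 (10, median 1.73, adjusted p = 6.4e-13) and complement genes in 12 of 13 (12, median 2.85, adjusted p = 1.3e-17). Fcgr2b, an inhibitory Fc receptor, rose by 5.27 ± 0.24 and C1qb by 4.36 ± 0.26. Reactive astrocyte genes rose in 15 of 16 cases (15 adjusted over the list alone, median 1.79, adjusted p = 6.1e-16). Gfap rose by 0.93 ± 0.11, Vim by 2.03 ± 0.13 and the ferroxidase gene Cp by 3.43 ± 0.19. The A1-type list had 5 of 9 genes higher and 1 lower (5 and 1 adjusted over the list alone, median 1.05, adjusted p = 3.3e-04, adjusted p = 0.0916 with an estimated correlation), with Serping1, which inhibits complement C1, at 2.97 ± 0.22. In the A2-type list 5 of 10 rose (5, median 0.69, adjusted p = 0.0015, adjusted p = 0.147 with an estimated correlation). Homeostatic astrocyte genes were split, 4 of 15 up and 4 down (5 and 4 adjusted over the list alone, adjusted p = 0.523), with a median of 0.09, a negative mean and an upward test. The gap junction gene Gja1 rose by 0.97 ± 0.12 and Mlc1 by 1.56 ± 0.12, and Kcnj10 fell by 1.58 ± 0.19.

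Interferon response genes rose in 22 of 25 cases at 28 d (23 adjusted over the list alone, median 2.13, adjusted p = 9.4e-14, adjusted p = 0.0685 with an estimated correlation), with Mx1 at 4.51 ± 0.50, Rsad2 at 4.38 ± 0.41 and Bst2 at 2.13 ± 0.22. Viral sensing genes rose in 11 of 14 cases (11 adjusted over the list alone, median 1.40, adjusted p = 6.7e-10). Antigen presentation genes rose in 10 of 15 cases (10, median 1.03, adjusted p = 3.8e-07, adjusted p = 0.0640 with an estimated correlation). Cytokine and chemokine genes rose in 13 of 24 with 1 lower (13 and 1, median 0.61, adjusted p = 6.2e-07). The chemokine gene Cxcl14 rose by 4.10 ± 0.16 and Ccl3 by 4.12 ± 0.35. Cell division genes rose in 13 of 17 cases (15 adjusted over the list alone, median 0.91, adjusted p = 1.3e-06, adjusted p = 0.0983 with an estimated correlation), with Mki67 at 1.95 ± 0.31. T and NK cell genes rose in 3 of 20 cases (3, median 0.03, adjusted p = 0.329), with Cd8b at 4.65 ± 0.40, Cd8a at 2.59 ± 0.57 and Cd6 at 0.62 ± 0.16. B and plasma cells had 1 of 7 genes higher, Cd22 at 2.41 ± 0.36 (1, adjusted p = 0.523, median -0.03 with an upward mean and test). Neutrophils had 2 of 12 higher (1, adjusted p = 0.368, median -0.04 with an upward mean and test), with Csf3r at 2.67 ± 0.22.

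Neuronal genes fell in 19 of 19 cases (19 adjusted over the list alone, median -1.39, adjusted p = 4.5e-13, adjusted p = 0.0983 with an estimated correlation), with Slc17a6 at -2.15 ± 0.28 and the sodium channel gene Scn1a at -1.80 ± 0.27. Motor neuron genes fell in 4 of 9 cases (4, median -0.37, adjusted p = 0.0328, adjusted p = 0.195 with an estimated correlation), among them Slc18a3, the vesicular acetylcholine transporter, by 1.35 ± 0.28. The list did not pass without injured replicate 3 (adjusted p = 0.0562). Myelinating oligodendrocyte genes fell in 10 of 13 cases (10 adjusted over the list alone, median -0.74, adjusted p = 1.6e-07, adjusted p = 0.0640 with an estimated correlation), with Fa2h at -2.32 ± 0.19 and Ugt8, which makes galactosylceramide, at -1.74 ± 0.14. Precursor genes were split, 2 of 8 up and 2 down (2 and 2, median 0.12, adjusted p = 0.523), with the complement-like gene C1ql1 at 1.48 ± 0.18. Schwann cell genes rose in 4 of 10 cases (4, median 0.48, adjusted p = 0.0132, adjusted p = 0.206 with an estimated correlation), among them Egr2, a transcription factor of Schwann cell myelination, by 0.97 ± 0.21. Fibrotic matrix genes rose in 2 of 14 cases (2, median 0.50, adjusted p = 0.0225, adjusted p = 0.594 with an estimated correlation), and Col1a1 differed by 0.48 ± 0.38 (adjusted p = 0.395). The fibrotic matrix list did not pass without injured replicate 2 (adjusted p = 0.0663) or 3 (adjusted p = 0.0560). With only the groups compared in the fit, its genes Postn (1.41, adjusted p = 0.0038) and Bgn (0.87, adjusted p = 0.0188) also passed. Proteoglycans and tenascins were 5 of 15 higher and 5 lower (5 and 5, adjusted p = 0.953, median 0.06 with a downward mean and test). Ependymal cells had 2 of 9 higher (3, median 0.25, adjusted p = 0.113). Endothelium and pericytes had 1 of 15 higher and 1 lower (1 and 1, adjusted p = 0.953, median -0.05 with an upward test), skeletal muscle had 2 of 12 lower (1, median -0.10, adjusted p = 0.523) and erythroid cells 0 of 8 in either direction (0, median -0.49, adjusted p = 0.228). The ciliogenesis regulator Foxj1 rose by 0.95 ± 0.18.

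At 28 d 6962 transcript clusters passed, 3250 higher and 3712 lower, of which 1229 and 1016 changed at least 2-fold. The share of higher calls, 46.7%, was 52.8% after cyclic loess. Again 17 lists passed, 13 upward and 4 downward, and 7 also passed with an estimated correlation. Of the clusters higher at 7 d and at 28 d, 2546 were shared, where independent lists of those sizes would share 474, and of the lower ones 3089 were shared against 674. Clusters that passed in opposite directions numbered 2 and 8. Both comparisons used the same uninjured arrays.

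Injury alone at 28 d was then compared directly with injury alone at 7 d. The cell division list passed downward between these times and the lists of ependymal cells and homeostatic astrocytes passed upward, the last of them not with an estimated correlation (adjusted p = 0.0710). In the cell division list 13 of 17 genes fell (16 adjusted over the list alone, median -1.30, adjusted p = 3.6e-30, adjusted p = 0.0019 with an estimated correlation), with Mki67 at -2.13 ± 0.31, Rrm2 at -2.03 ± 0.23 and Tpx2 at -1.54 ± 0.20. Ependymal cell genes rose in 3 of 9 cases (4 adjusted over the list alone, median 0.34, adjusted p = 8.8e-05, adjusted p = 0.0115 with an estimated correlation), among them the ciliary genes Tmem212 by 1.18 ± 0.20 and Spef2 by 0.83 ± 0.19. Homeostatic astrocyte genes rose in 6 of 15 cases (10 adjusted over the list alone, median 0.49, adjusted p = 3.6e-09, adjusted p = 0.0710 with an estimated correlation), with Gja1 at 0.76 ± 0.12, Mlc1 at 0.68 ± 0.12 and Slc4a4 at 0.63 ± 0.13.

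Among genes whose groups did not overlap, those that rose most were Lcat, the plasma cholesterol-esterifying enzyme, by 2.07 ± 0.26, the choroid plexus peptide gene Ecrg4 by 2.03 ± 0.25, Cxcl14 by 1.98 ± 0.16 and the growth factor gene Igf2 by 1.93 ± 0.28. They were followed by the carbonic anhydrase gene Car2 by 1.83 ± 0.37, Tnfaip6 by 1.80 ± 0.33, the oxysterol hydroxylase gene Cyp7b1 by 1.76 ± 0.13 and Acsm5 by 1.74 ± 0.24. Of such genes those that fell most were Mmp8 by 4.62 ± 0.66, the pancreatic lipase gene Pnlip by 3.05 ± 0.20, the calcium-sensing receptor gene Casr by 2.45 ± 0.29, followed by the macrophage complement receptor gene Vsig4 by 2.44 ± 0.51, the neuropeptide gene Trh by 2.18 ± 0.43 and Mki67. Reactive astrocyte genes rose in 4 of 16 cases and fell in 1 (5 and 2 adjusted over the list alone, median 0.37, adjusted p = 0.0156, adjusted p = 0.372 with an estimated correlation). Gfap rose by 0.47 ± 0.11 (adjusted p = 0.0095), Cp by 1.44 ± 0.19 and the heat shock gene Hspb1 by 1.67 ± 0.34, and Lcn2 fell by 2.48 ± 0.54. The list did not pass without replicate 3 at 28 d (median 0.17, adjusted p = 0.0882), its median was 0.21 without replicate 5 at 7 d, and Gfap did not pass after quantile normalization (0.41, adjusted p = 0.0720). Proteoglycans and tenascins had 3 of 15 genes lower (2 higher and 3 lower adjusted over the list alone, median -0.06, adjusted p = 0.232), with Tnr at -1.13 ± 0.18 and Vcan at -1.02 ± 0.24. Gpr17 fell by 1.19 ± 0.18 and C1ql1 rose by 0.72 ± 0.18 in the precursor list (1 higher and 2 lower of 8, 1 and 3 adjusted over the list alone, median -0.13, adjusted p = 0.0936). C1ql1 did not pass without replicate 1 (adjusted p = 0.104) or 5 (adjusted p = 0.0606) at 7 d. It did not pass either without replicate 1 (adjusted p = 0.0518), 3 (adjusted p = 0.0614) or 4 (adjusted p = 0.0963) at 28 d, or with only these groups in the fit (adjusted p = 0.0660).

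Further lists that passed downward had few or no single genes past the test. These were cholesterol synthesis (1 of 13, 7 adjusted over the list alone, median -0.43, adjusted p = 2.1e-07, adjusted p = 0.200 with an estimated correlation). They also included fibrotic matrix (0 of 14, 3 adjusted over the list alone, median -0.67, adjusted p = 5.2e-05, adjusted p = 0.407 with an estimated correlation) and interferon response (0 of 25, 0, median -0.51, adjusted p = 0.0021, adjusted p = 0.506 with an estimated correlation). The same held for viral sensing (0 of 14, 0, median -0.34, adjusted p = 0.0027, adjusted p = 0.372 with an estimated correlation), neutrophils (1 of 12, 2, median -0.43, adjusted p = 0.0028, adjusted p = 0.200 with an estimated correlation) and homeostatic microglia (0 of 10, 4, median -0.23, adjusted p = 0.0048, adjusted p = 0.200 with an estimated correlation). With only these groups in the fit, further genes of these lists fell past the test, of the at most 4 per list that were followed. They were Col1a1 (adjusted p = 0.0043), Postn (adjusted p = 0.0230) and Col3a1 (adjusted p = 0.0480) of fibrotic matrix, Ifi47 (adjusted p = 0.0227) of interferon response and Mvd (adjusted p = 0.0451) of cholesterol synthesis. Without replicate 1 at 7 d neither interferon response (median -0.22, adjusted p = 0.0816) nor viral sensing (median -0.22, adjusted p = 0.0593) passed. Without replicate 4 at 7 d interferon response did not pass (median -0.23, adjusted p = 0.0986). Its median was -0.28 without replicate 2 at 28 d, and that of neutrophils -0.13 without replicate 2 at 7 d. Single interferon genes passed in other such runs, Ifit1 (-4.19, adjusted p = 0.0027) without replicate 3 at 28 d and Oasl2 (-1.26, adjusted p = 0.0478) without replicate 5 at 7 d. Mx1 passed without replicate 2 (adjusted p = 0.0382) or 5 (adjusted p = 0.0323) at 7 d or replicate 5 at 28 d (adjusted p = 0.0228). Some genes of fibrotic matrix and cholesterol synthesis also gained calls in such runs. The complement list had 2 of 13 genes higher and 3 lower (3 and 3, median -0.14, adjusted p = 0.499), with Serping1 at 1.10 ± 0.22 and the anaphylatoxin receptor gene C3ar1 at -1.11 ± 0.23. Myelinating oligodendrocytes (1 of 13 lower, 1 higher and 6 lower adjusted over the list alone, median -0.17, adjusted p = 0.0527), Schwann cells (1 of 10 higher, 2 and 2 adjusted over the list alone, median 0.37, adjusted p = 0.0731), endothelium and pericytes (1 of 15 higher, 2 adjusted over the list alone, median 0.07, adjusted p = 0.0936) and phagocytes and lysosome (0 of 22, median -0.18, adjusted p = 0.385) did not pass. The other lists had adjusted p of 0.358 or more, and the median and the mean or test differed in sign for antigen presentation, cytokines and chemokines, neurons and motor neurons. In total 688 clusters passed, 373 higher and 315 lower, with 90 and 126 of at least 2-fold. Of the 10 lists past the test, 3 upward and 7 downward, only cell division and ependymal cells also passed with an estimated correlation.

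The series asks whether the astrocyte-selective vector changes the tissue response to contusion, and each vector group was compared with injury alone at its own time. At 7 d 0 of 23188 transcript clusters passed in limma, with 1607 at an unadjusted p under 0.05 where 1159 are expected by chance, and the lowest adjusted p was 0.524. Other splits of the same arrays gave a median of 1413 such clusters, so 1607 is no clear excess. Gfap differed by -0.02 (95% confidence interval -0.24 to 0.20), Vim by -0.04 (-0.31 to 0.23) and Aqp4 by -0.08 (-0.33 to 0.18). Intervals for the microglial and leukocyte genes Aif1 (-0.13 to 0.87), Ptprc (-0.27 to 0.63) and Cd3e (-0.06 to 0.98) and for the cytokine genes Tnf (-0.49 to 0.34) and Il1b (-0.56 to 0.19) stayed within 2-fold. Intervals went beyond 2-fold for Lcn2 (-1.57 to 0.67), Cd68 (-0.27 to 1.10), Cd8a (-1.21 to 1.13), Ccl2 (-0.13 to 1.42), Isg15 (-1.93 to -0.06), Mx1 (-2.48 to -0.43) and C3 (-1.31 to -0.15). The arrays ran from 11.6 to 14.5 for Mx1 in injury alone and from 10.7 to 11.8 in the vector group. The pooled interval of Mx1 may therefore be too narrow for these groups. Among named genes the smallest unadjusted p values belonged to Pglyrp3 (-0.73), Col4a4 (0.60), Coq9 (0.50) and Hpn (-0.61), none of which passed (adjusted p = 0.524 for each). Over all clusters, dim and unnamed ones included, 22585 (97.4%) had a 95% interval within 2-fold either way and 16340 (70.5%) within 1.5-fold. Of the 20 genes fixed for every comparison, 13 lay within 2-fold and 7 within 1.5-fold.

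At the level of lists 8 passed camera at 7 d with its preset correlation, 6 upward and 2 downward, and 0 passed with an estimated correlation, in the rotation test fry (lowest adjusted p = 0.554) or in an exact permutation of list means (lowest adjusted p = 0.643). No single gene of any list passed. Phagocyte and lysosome genes were higher in 22 of 22 cases (median 0.36, adjusted p = 4.3e-05, adjusted p = 0.526 with an estimated correlation) and antigen presentation genes in 15 of 15 (median 0.34, adjusted p = 4.3e-05, adjusted p = 0.515 with an estimated correlation). Endothelium and pericytes (median 0.14, adjusted p = 0.0013, adjusted p = 0.515 with an estimated correlation), cell division (median 0.20, adjusted p = 0.0066, adjusted p = 0.526 with an estimated correlation) and Schwann cells (median 0.26, adjusted p = 0.0073, adjusted p = 0.526 with an estimated correlation) were also higher. Interferon response genes were lower in the vector group (median -0.57, adjusted p = 3.6e-04, adjusted p = 0.534 with an estimated correlation), with 2 higher and 5 lower when adjusted over the list alone. Neuronal genes were lower as well (median -0.15, adjusted p = 0.0239, adjusted p = 0.765 with an estimated correlation). In the interferon list Mx1 differed by -1.46, Oas1a by -1.26 and Cmpk2 by -0.88, and the interferon-gamma-inducible genes Cxcl9 and Irf1 by 1.97 and 1.04. Vector replicates 1 and 5 stood at 10.9 and 8.53 for Cxcl9 and the other 3 at 5.36 to 6.57, and without replicate 1 its difference was 1.11. Interferon response did not pass without injury-alone replicate 1 (median -0.41, adjusted p = 0.0694) or 4 (median -0.39, adjusted p = 0.0758) or vector replicate 3 (median -0.47, adjusted p = 0.0933). Phagocytes and lysosome did not pass without injury-alone replicate 2 (median 0.16, adjusted p = 0.0550), nor Schwann cells without vector replicate 5 (median 0.16, adjusted p = 0.0984). The phagocyte median was 0.18 to 0.21 without injury-alone replicate 4 or vector replicate 2 or 5, and that of antigen presentation 0.57 without vector replicate 3. Cell division did not pass without injury-alone replicate 2 or 4 or vector replicate 2 or 5 (median 0.05 to 0.16, adjusted p = 0.0888 to 0.488), and its median was 0.31 without vector replicate 3. Neurons did not pass without injury-alone replicate 2, 3 or 4 or vector replicate 2 or 5 (adjusted p = 0.0781 to 0.492), and without vector replicate 5 their median turned to 0.06. It was -0.26 to -0.23 without injury-alone replicate 1 or 5 or vector replicate 1 or 3.

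Skeletal muscle genes moved with these lists at 7 d. They were higher in 12 of 12 cases (median 0.49, adjusted p = 7.7e-05, adjusted p = 0.526 with an estimated correlation), and Acta1, the skeletal muscle actin, was at 9.02 ± 3.45 (SD) in the vector group against 5.76 ± 0.35 in injury alone. Replicates 1 and 3 of the vector group at 7 d stood apart in these genes, and without replicate 3 the list did not pass (median 0.13, adjusted p = 0.489), while without replicate 2 its median was 0.77. The list mean was 7.03 and 9.38 in these arrays, 7.12 in replicate 2 of the vector group at 28 d and at most 6.57 in the others. Without both arrays, a setting chosen after seeing the data, 13 lists passed, the muscle median was -0.18 and the medians of phagocytes and lysosome, antigen presentation and interferon response were 0.59, 0.43 and -0.65. The 3 astrocyte lists of reactive, A1-type and A2-type genes had medians of 0.02, 0.15 and 0.13 (adjusted p = 0.413, 0.661 and 0.258), and complement and cytokines and chemokines medians of 0.20 and 0.03 (adjusted p = 0.181 and 0.519). Viral sensing and oligodendrocyte precursors had a median and a mean of opposite sign. Adjusted over the list alone, 1 cell division gene and 1 muscle gene were higher.

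At 28 d 0 of 23188 clusters differed between the vector group and injury alone in limma, with 894 at an unadjusted p under 0.05 and a lowest adjusted p of 0.398. Without vector replicate 4, 3 clusters and 3 lists passed. Leaving out 1 array at a time gave 0 lists in only 3 runs and at least 1 list in every other run. Without the 3 arrays highest in muscle transcripts (replicate 2 of this group and replicates 1 and 3 at 7 d), a setting chosen after seeing the data, antigen presentation (median 0.10, adjusted p = 0.0097), neurons (-0.24, adjusted p = 0.0223) and skeletal muscle (-0.21, adjusted p = 0.0047) passed. The 95% interval of the difference ran from -0.22 to 0.22 for Gfap and from -0.27 to 0.27 for Vim. Intervals outside 2-fold were those of Lcn2 (-0.62 to 1.61), Cd8a (-1.22 to 1.13), Cxcl10 (-1.55 to 0.12), Isg15 (-1.27 to 0.60), Mx1 (-1.72 to 0.33) and Col1a1 (-0.35 to 1.23), and the other 14 of the 20 genes fixed for every comparison stayed within it. Among named genes Xcr1, a chemokine receptor of dendritic cells, had the smallest unadjusted p (difference 0.77, adjusted p = 0.457), followed by Rnf41 (0.41), Cfap95 (-0.69) and Phlda1 (-0.52), none of which passed. Of all clusters, dim and unnamed ones included, 22772 (98.2%) lay within 2-fold and 17672 (76.2%) within 1.5-fold, the latter against 8 of the 20 fixed genes. No list passed (lowest adjusted p = 0.108), and the lowest adjusted p with an estimated correlation was 0.95. Class II genes of the antigen presentation list, RT1-Da (95% interval 0.47 to 2.53) and Cd74 (0.52 to 2.35), passed only when adjusted over the list alone (2 higher), where the list median was -0.01 and its mean and test were upward. The medians of interferon response and fibrotic matrix were -0.33 and 0.28. Median and mean or test also differed in sign for cytokines and chemokines, cholesterol synthesis, cell division and skeletal muscle.

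The vector effect averaged over both times gave 0 clusters past the test (1525 at an unadjusted p under 0.05, lowest adjusted p = 0.470), and 23058 clusters (99.4%) had an interval within 2-fold. Isg15 and Mx1 were the genes of the fixed 20 whose intervals went beyond it. Of 6 lists past camera, 4 were upward, antigen presentation (median 0.19, adjusted p = 3.2e-05, 3 higher adjusted over the list alone), skeletal muscle (0.27, adjusted p = 0.0067), Schwann cells (0.21, adjusted p = 0.0143) and phagocytes and lysosome (0.13, adjusted p = 0.0267), and 2 downward, interferon response (-0.36, adjusted p = 1.8e-04, 2 higher and 6 lower adjusted over the list alone) and neurons (-0.12, adjusted p = 0.0361). With an estimated correlation 0 passed (lowest adjusted p = 0.735). Leaving out any of 9 arrays ended the call of phagocytes and lysosome (median 0.025 to 0.11, adjusted p = 0.0596 to 0.354), and any of 10 that of neurons (median -0.12 to -0.0020, adjusted p = 0.0501 to 0.928). The lowest phagocyte median was that without injury-alone replicate 2 at 7 d, and the neuron median closest to 0 that without vector replicate 5 at 7 d. The phagocyte median was 0.21 without injury-alone replicate 1 and 0.23 without vector replicate 3 at 7 d, and that of antigen presentation 0.10 without vector replicate 1 at 7 d. For phagocytes these were injury-alone replicates 2, 3 and 4 at 7 d and 1 and 2 at 28 d, and vector replicates 2 and 5 at 7 d and 4 and 5 at 28 d. For neurons they were injury-alone replicates 2, 3 and 4 at 7 d and 1 and 5 at 28 d, and vector replicates 2 and 5 at 7 d and 3, 4 and 5 at 28 d. Skeletal muscle did not pass without vector replicate 3 at 7 d (median 0.13, adjusted p = 0.655) or 2 at 28 d (median 0.16, adjusted p = 0.0768), nor Schwann cells without vector replicate 5 at 7 d (adjusted p = 0.0894) or 2 at 28 d (adjusted p = 0.0727). Without the 3 arrays highest in muscle transcripts 12 lists passed, the muscle median turned to -0.20 (adjusted p = 0.0063) and Schwann cells did not pass (adjusted p = 0.0902). A change of the vector effect from 7 d to 28 d was found for 0 clusters (924 at an unadjusted p under 0.05, lowest adjusted p = 0.9998). In that test 3 lists passed, all with a lower vector effect at 28 d than at 7 d, namely phagocytes and lysosome (median -0.38, adjusted p = 4.1e-04), endothelium and pericytes (-0.24, adjusted p = 0.0038) and skeletal muscle (-0.53, adjusted p = 0.0052). Each of them had adjusted p = 0.781 with an estimated correlation. Phagocytes and lysosome did not pass without injury-alone replicate 2 at 7 d (median -0.29, adjusted p = 0.0946), and skeletal muscle without vector replicate 3 at 7 d (median -0.10, adjusted p = 0.586) or 5 at 28 d (adjusted p = 0.0534). The phagocyte median was -0.23 without injury-alone replicate 4 at 7 d, and that of endothelium and pericytes -0.37 without injury-alone replicate 4 at 28 d. Without the 3 arrays 5 lists passed, skeletal muscle (median -0.04, adjusted p = 0.413) not among them.

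**Figure D2:**
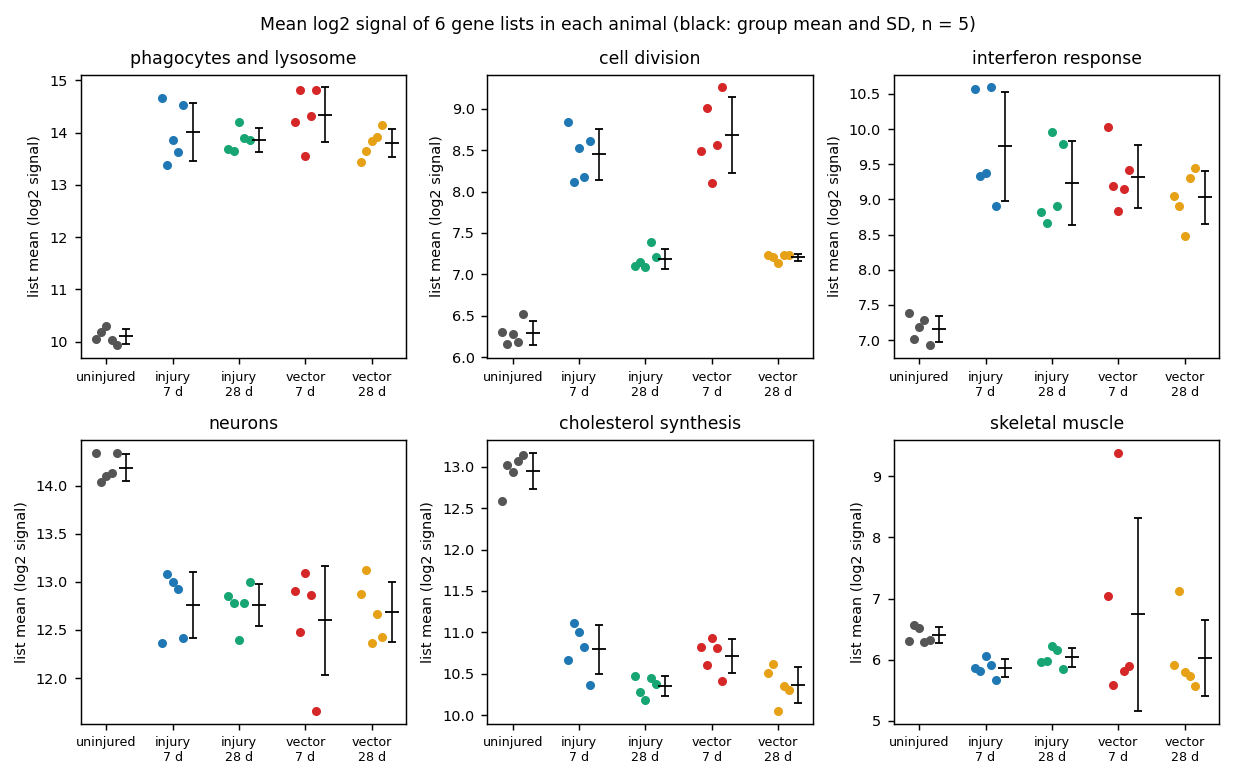
Mean log2 signal of 6 gene lists in each of the 25 animals (coloured points), with group mean and SD in black (n = 5). Uninjured animals lie apart from injured ones for phagocytes, cell division, interferon response, neurons and cholesterol synthesis, the vector groups overlap injury alone, and replicates 1 and 3 of the vector group at 7 d and replicate 2 at 28 d have the highest skeletal muscle means.

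A test of the whole profile set the summed squared difference of group means against all relabellings of the arrays. Vector and injury alone did not separate at 7 d (exact permutation p = 0.413), at 28 d (exact permutation p = 0.286) or over both times (exact permutation p = 0.345, 63504 relabellings). Injury separated from uninjured cord at both times with an exact permutation p of 0.0079, the smallest that 5 against 5 arrays can give. Genes were also simulated as changed, 50 per fold and time, with noise independent between genes. For 7 d 38% were recovered at 1.5-fold and 88% at 2-fold, and for 28 d 20% and 84%. Recovery may differ in the real arrays, where genes may vary together.

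Against uninjured cord, the vector groups gave 8785 clusters at 7 d (3942 higher, 4843 lower) and 7547 at 28 d (3482 higher, 4065 lower), with 44.9% and 46.1% of the calls higher, or 52.5% and 52.7% after cyclic loess. Of the clusters higher in injury alone at 7 d, 3147 were also higher with the vector, where independent lists would share 575, and 3635 were lower in both against 879. At 28 d 2900 and 3246 were shared against 488 and 651, and 0 passed in opposite directions at either time. Across transcript clusters, which are not independent replicates, the differences from uninjured cord correlated between vector and injury alone at r = 0.964 at 7 d and r = 0.963 at 28 d. Unchanged groups simulated with a shared simulated control gave r = 0.50 and 0.499. This is the r that a shared control gives without any injury response, so it does not bear on an effect of the vector. The covariances were 0.567 and 0.455 against 0.0191 in both simulations, and with the uninjured arrays split between the comparisons r was 0.892 to 0.920 at 7 d and 0.885 to 0.903 at 28 d. With the vector, 28 d differed from 7 d in 1259 clusters (614 higher, 645 lower), and the cell division list fell in 16 of 17 genes (17 adjusted over the list alone, median -1.37, adjusted p = 1.7e-30). Lists that passed numbered 19 for the vector at 7 d against uninjured, 16 at 28 d and 12 between the times, and 9, 9 and 2 of them passed with an estimated correlation.

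**Figure D3:**
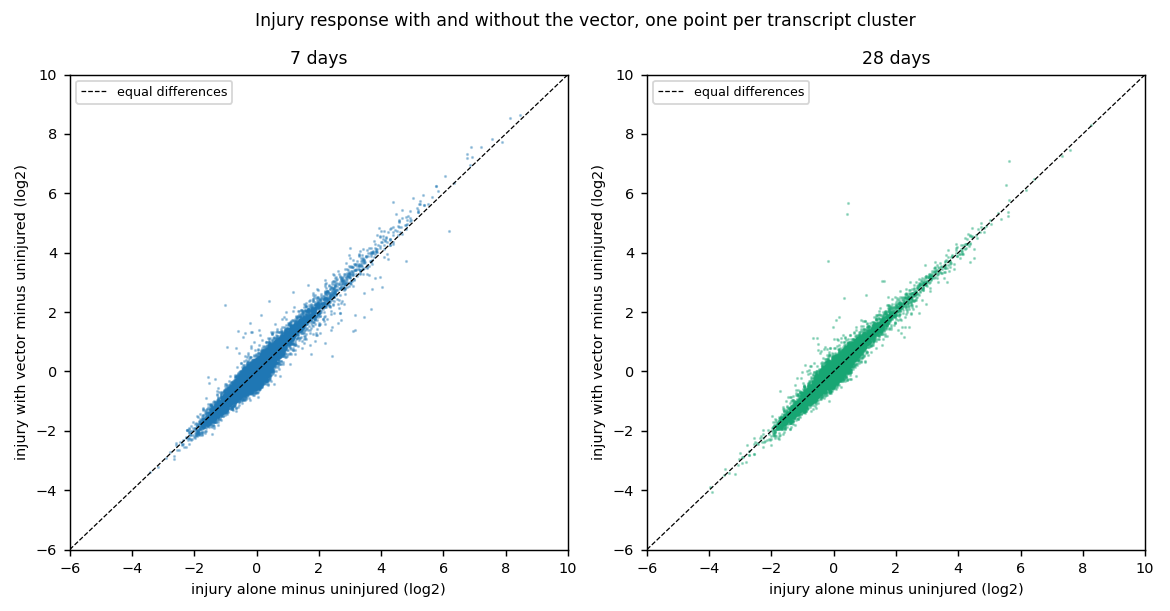
Log2 difference from uninjured cord with the vector (vertical axis) against that of injury alone (horizontal axis) at 7 d (left) and 28 d (right), with 1 point per transcript cluster and a dashed line of equal differences. Points follow the line, with r = 0.964 and r = 0.963 across clusters.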

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

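The test with an estimated correlation was planned, and its use to weigh the vector's list shifts was chosen only after the results were seen. The tests of those shifts without muscle-bearing arrays and of the cell division list, those of the muscle transcripts and those of the unnamed clusters were chosen only after the results were seen, as were the counts over splits of the arrays.

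List shifts with the vector at 7 d. The 8 list calls rest on the preset correlation, since the lowest adjusted p with an estimated correlation was 0.515, and list genes that vary together between animals are therefore a candidate explanation. Staying past the test at that preset correlation shows only that a call does not depend on a setting, and argues against no cause of the shifts. Without the 2 arrays with muscle transcripts 7 of the 7 other lists stayed past it, while the skeletal muscle list itself fell to a median of -0.18. An injury score was the mean of clusters that rose with injury alone at 7 d minus that of clusters that fell, list genes left out. It was scaled to 0 in uninjured animals and 1 in injury alone at 7 d, so it measures expression and not lesion extent. The score differed by 0.0567 between the groups (exact permutation p = 0.635). With this score as a covariate in a fit of both groups alone, 5 of the 7 stayed past the test. The median of phagocytes and lysosome went from 0.36 to 0.17 (adjusted p = 0.0060), and the score could itself be changed by the vector. In that fit cell division (median 0.20 and adjusted p = 0.0062 without the score, 0.10 and adjusted p = 0.122 with it) and homeostatic microglia (0.14 and adjusted p = 0.0236 without, 0.07 and adjusted p = 0.109 with it) lost their calls. Since the score was built from clusters called in injury alone at 7 d, 1 of the groups compared, this cannot decide whether the extent of injury accounts for these lists. Neurons, 1 of the 7, passed neither without the score (adjusted p = 0.0683) nor with it (adjusted p = 0.809). An effect of the vector or the injection stays open.

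Muscle transcripts in replicates 1 and 3 of the vector group at 7 d. In replicate 3, 9 of 12 muscle genes stood at least 2-fold above their median over all arrays, with log2 signals of 13.3 for Myh4 and 13.8 for Acta1, so muscle tissue in the sample is a candidate source (of the 12, Pvalb is also expressed by cord, with a median of 11.9 over all arrays). In replicate 1, with 4 of 12 such genes, Myh4 stood -0.24 from its median while Acta1 stood 5.17 above, which argues against the same kind of muscle tissue in both. As a test of a wrong label, mean correlations were taken without the muscle list genes. Replicate 3 correlated at 0.985 with replicates 2, 4 and 5 of its group. With the closest other time or uninjured group it correlated at 0.988 (smallest margin -0.00287), as a sample of another group might. With injury alone at 7 d, however, the value was 0.989. A time score, chosen after these correlations had been seen, put the higher of both arrays at 0.159, where injury alone spans -0.174 to 0.224 at 7 d and 0.931 to 1.06 at 28 d, which argues against a 28 d sample, and injury scores of 0.958 and 0.824 against at most 0.0521 in uninjured animals argue against an uninjured one. Replicate 2 of the vector group at 28 d (5 of 12 such genes, list mean 7.12 against 7.03 in replicate 1 at 7 d) and uninjured replicate 3 (4 of 12, mean 6.53) were not tested in this way, and no biological explanation was tested.

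Unnamed clusters in the vector group at 28 d. In replicates 1, 2 and 3 the clusters TC0600003269.rn.2 and TC0400004145.rn.2 stood far above the other arrays, with gaps of 6.68 and 4.74 log2 units to the next array. A further 2 unnamed clusters stood apart only in replicates 2 and 3 (13.3 and 13.2, and 11.0 and 9.78) and were at 5.29 and 5.27 in replicate 1. Scaling of whole arrays is argued against by upper quartiles that range over 0.235 log2 units. The difference between the clusters high in all 3 arrays ranged over 1.65 log2 units there, which decides nothing on a single transcript read by both, since they were picked for being high in the same arrays. By smaller amounts both clusters were also higher than in most arrays in injury-alone replicate 5 at 28 d (10.7 and 9.34), without vector, and in vector replicate 1 at 7 d (10.2 and 9.96). A link with the vector or injection cannot be told apart from chance, since Fisher's exact test of 3 of 10 vector arrays against 0 of 15 others gave p = 0.0522 on clusters picked for the pattern.

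Single animals stood apart from the other 4 of their group by the ratio of gap to range given in each case, which happens in about 1 in 20 groups by chance: 6 of 135 list means and 19 of 335 group values of named genes were found, where 6.75 and 16.75 are expected. For list means the ratios were 0.793 for neutrophils and 0.788 for Schwann cells in replicate 2 of injury alone at 7 d, 0.847 for fibrotic matrix in its replicate 1, 0.728 for neutrophils in replicate 4 of the vector group at 7 d, 0.791 for cytokines and chemokines in uninjured replicate 1 and 0.779 for skeletal muscle in replicate 2 of the vector group at 28 d. In replicate 4 of injury alone at 7 d they were 0.776 for Lcn2, 0.732 for Tnf, 0.803 for Hspb1, 0.807 for Tmem212, 0.739 for Tnfaip6 and 0.865 for Timp1, and in its replicate 3 the ratio was 0.886 for Cyp7b1. In injury alone at 28 d they were 0.826 for Tnr in replicate 2, 0.789 for Abca1 and 0.820 for Egr2 in replicate 3, 0.801 for Fcrl2 in replicate 4 and 0.724 for Foxj1 in replicate 5. Uninjured replicate 5 had 0.713 for Abca1 and 0.837 for Lilrb4, and replicate 1 had 0.744 for Cd86. In the vector groups they were 0.714 for Cd68 and 0.724 for Cd8a in replicate 3 and 0.852 for Coq9 in replicate 2 at 7 d, and 0.758 for RT1-Da in replicate 4 at 28 d.

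Injury alone at 28 d differed from injury alone at 7 d in 688 clusters and 10 lists by the direct test, of which 2 lists also passed with an estimated correlation. The single uninjured group carries no time in the labels. A change in the effect of injury can therefore not be told apart from an effect of time or age alone. The vector effect differed between the times for phagocytes and lysosome (adjusted p = 4.06e-04 in limma's camera), endothelium and pericytes (adjusted p = 0.00379) and skeletal muscle (adjusted p = 0.00515). With an estimated correlation 0 lists passed (adjusted p = 0.781 for each of the 3). Phagocytes and lysosome did not pass without injury-alone replicate 2 at 7 d (adjusted p = 0.0946), nor skeletal muscle without vector replicate 3 at 7 d (median -0.10, adjusted p = 0.586), vector replicate 5 at 28 d (adjusted p = 0.0534) or the 3 arrays highest in muscle transcripts (adjusted p = 0.413).

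Of 100 splits of the arrays per comparison, the real one included, 1 gave as many genes for injury at 7 d (7590 against 3039 at most in the others), injury at 28 d (6962 against 2080), 28 d against 7 d (688 against 6), the vector groups against uninjured at 7 d (8785 against 5829) and 28 d (7547 against 3148) and between the vector groups (1259 against 254). This argues against chance there, as far as 100 splits can show. For the vector against injury alone the count was 0 in limma, which every split reaches, so counts at an unadjusted p under 0.05 were compared. At least as many as the real 1607 at 7 d came from 42 of the 100 splits (4240 at most in the others), as the 894 at 28 d from 39 (1617), as the 1525 for both times from 16 (4263) and as the 924 for the change between times from 69 (4288), so chance is not excluded. Medians of the others were 1413 at 7 d, 841 at 28 d, 1037 for both times and 1106 for the change between times. Past the adjusted test the highest other split gave 798 genes at 7 d, 1 at 28 d, 1040 for both times and 961 for the change between times, with a median of 0 over the others, and the splits with many genes may point to a structure of the samples, which was not tested.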

How the results depend on the processing

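The runs without 2 arrays that carry muscle transcripts (vector replicates 1 and 3 at 7 d) or 3 (also replicate 2 at 28 d) and the permutation of list means were chosen only after the results were seen. Of the values of named genes under the alternatives, 19349 stayed on their side of the threshold without a reversal, 115 lost the call, 96 gained it and 0 reversed. Of list results, by the direction of the list test, 4330 stayed so, 145 lost the call, 161 gained it and 8 reversed. Values past the test in neither run count as unchanged whatever their sign. For the vector comparisons, where no named gene passed, a change of sign could therefore not be counted and no call could be lost. Their values are among the 19349. All lost and gained calls came from the comparisons of injury alone, among them 61 losses for 28 d against 7 d with 1 array left out. Counts of genes stayed within 1.5 times in 218 cases and moved in 14, and the cause was not tested. At an unadjusted p under 0.05 with at least 2-fold change the counts were 2554 for injury at 7 d, 2255 at 28 d, 285 for 28 d against 7 d, 28 for the vector at 7 d, 16 at 28 d, 9 for both times, 41 for the change between times, 2961 and 2534 for the vector groups against uninjured and 438 between them. At adjusted p under 0.01 they were 356 for 28 d against 7 d and 591 between the vector groups, where using only these groups gave 726. Lists past the test with an estimated correlation numbered 9 and 7 for injury at 7 d and 28 d, 2 for 28 d against 7 d, and 0 for the vector at 7 d, both times and the change between times. Fry gave 6 for 28 d against 7 d and 0 for those 3 vector comparisons, and the exact permutation of list means gave 6 for 28 d against 7 d and 0 for the vector at 7 d. Without the 2 arrays 13 lists passed for the vector at 7 d, 10 for both times and 6 for the change between times, and the skeletal muscle median reversed to -0.175, -0.0418 and 0.131. Without the 3 arrays 13 lists passed at 7 d, 3 at 28 d, 12 for both times and 5 for the change between times, and that median reversed to -0.175 at 7 d, -0.212 at 28 d and -0.202 for both times. With dim clusters left out 3 lists passed for both times, and with only the groups compared 1 passed for the vector at 28 d. Similarity of the injury responses with dim clusters left out was 0.975 at 7 d and 0.973 at 28 d. Leaving out 1 array gave 5 to 11 lists for the vector at 7 d, 0 to 3 lists and 0 to 3 genes at 28 d (3 without vector replicate 4), 3 (without vector replicate 5 at 7 d) to 10 lists for both times and 2 to 7 (without vector replicate 4 at 7 d) for the change between times. For the vector at 7 d the fibrotic matrix median then ran from -0.343 (without vector replicate 5) to 0.254 (without its replicate 3) and that of neurons from -0.256 (without injury-alone replicate 1) to 0.0629 (without vector replicate 5). With a replicate block 7514 genes changed at 7 d and 6818 at 28 d with injury, 657 between the times and 0 with the vector at either time. Lists numbered 18, 17, 10, 9 and 0 in these comparisons, so none of these counts moved by more than 1.5 times. Deviations of arrays with the same number had median correlations of -0.0881 to 0.0734 between groups, with single values from -0.265 to 0.237. They show no strong pairing by replicate number but cannot exclude that same-numbered samples were handled together. Cyclic loess moved the median of all clusters by at most 0.0943 and raised the share of higher calls for injury from 44.5% to 51.5% at 7 d and from 46.7% to 52.8% at 28 d, and for the vector groups against uninjured from 44.9% to 52.5% and from 46.1% to 52.7%. Signal over background was not at hand, so what dim clusters can show is not known.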

Other observations

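The gene families below, defined by the start of the gene symbol, were chosen only after the injury calls were seen, and adjusted p-values are limma's camera over 1242 families. Of 48 ribosomal protein genes of the large subunit 41 rose with injury at 7 d (median 0.65, adjusted p = 1.4e-13, adjusted p = 0.512 with an estimated correlation), with Rplp0 at 1.53 and Rpl39 at 1.33. Of 28 genes of the small subunit 26 rose (median 0.82, adjusted p = 2.5e-13, adjusted p = 0.410 with an estimated correlation), with Rps12 at 1.29. Genes of mitochondrial complex I fell in 27 of 40 cases (median -0.55, adjusted p = 7.7e-06, adjusted p = 0.585 with an estimated correlation), with Ndufs4 at -0.89. At 28 d 41 large subunit genes rose and 1 fell, 25 small subunit genes rose and 20 complex I genes fell.

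Potassium channel genes at 7 d were lower in 49 of 86 cases and higher in 5 (median -0.63, adjusted p = 2.0e-06, adjusted p = 0.506 with an estimated correlation), with Kcns3 at -2.23 and Kcnh7 at -2.02. Calcium channel genes fell in 16 of 24 cases (adjusted p = 6.8e-05, adjusted p = 0.506 with an estimated correlation), with Cacna2d3 at -1.78, and ionotropic glutamate receptor genes in 15 of 19 (adjusted p = 2.4e-05, adjusted p = 0.510 with an estimated correlation), with Grin2b at -1.66. GABA-A receptor genes were lower in 8 of 16 cases and higher in 1 (median -0.50, adjusted p = 0.0481, adjusted p = 0.626 with an estimated correlation). Sodium channel genes did not pass as a family (6 of 15 lower and 1 higher, median -0.28, adjusted p = 0.153). All 6 Fc gamma receptor genes rose (median 4.68, adjusted p = 2.4e-09, adjusted p = 0.282 with an estimated correlation), with Fcgr2a at 4.83. From 7 d to 28 d 5 of 20 glutathione transferase genes rose (median 0.38, adjusted p = 2.2e-05, adjusted p = 0.174 with an estimated correlation), with Gstm5 at 1.28. In the comparisons given here the median of each of these 10 families kept its sign with quantile and cyclic loess scaling.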
